A study of Mus musculus with 24 samples.

How the data were processed

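Gene counts were taken from the table of unfiltered raw counts per Ensembl gene that the authors deposited, with 46078 genes and 24 libraries. The deposited signal table, a depth-normalised version of a filtered count table, was used only to check what it held: each library's values equalled its deposited counts divided by 1 size factor, and those factors matched the median-ratio factors of DESeq to within 1.3e-07. The filtered table held 15140 genes, and 13938 of the 13955 genes above 0.5 CPM, the count scaled to a common library size, in at least 13 libraries were in it. The submitters' processing notes name Bowtie2, TopHat, TopHat2 2.1.1, HTSeq, DESeq, edgeR and the mouse build GRCm38. The role of each tool, most versions and the annotation release are not given in the sources used here. The reads themselves were not analysed here. The libraries were polyadenylated, single-end and not strand-specific, so counts of overlapping antisense genes and of close paralogs are uncertain.

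Each title carried a distinct animal tag, so each library was treated as 1 animal. Replicate numbers within a group follow accession order and pair nothing. Symbols came from the deposited table, and 193 of the 197 genes that lacked one were named from the GENCODE vM21 reference. Coordinates are the deposited locus with 1 added to the start. Of the 46078 genes, 45143 were in the reference, 87.3% of those had the same start and 87.0% the same chromosome and end.

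The groups, tests, lists, rule for naming genes and most alternatives were chosen before the data were examined, but the injury share was not among those tests. Genes above 0.5 CPM in at least 6 libraries were kept, which left 15456 genes, 14938 of them also in the filtered table. Counts were scaled by the trimmed mean of M-values (TMM) and fitted with the edgeR quasi-likelihood model (glmQLFit and glmQLFTest), with 1 coefficient for each of the 4 groups of 6 and all 24 libraries in the fit. There were 5 contrasts: DTR_PBS minus WT_PBS, DTR_PYR minus WT_PYR, DTR_PYR minus DTR_PBS, WT_PYR minus WT_PBS, and the interaction, which is the third minus the fourth. The p values are two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. CPM values in the text are TMM-scaled, with means and SD over the 6 libraries of a group. Log2 CPM used a prior count of 2. Software was R 4.3.3 with edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and sva 3.50.0.

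The rule for naming genes had 3 parts. The first took, among called genes with a mean of at least 5 CPM and no overlap between the groups' libraries, the 8 largest rises and the 8 largest falls, leaving out predicted and unnamed genes; where fewer than 4 such genes existed, the 8 smallest p values among genes of at least 5 CPM were taken as values. The second took up to 3 called members of each gene list, by p. The third gave Nppa, Nppb, Myh6, Myh7, Hbegf, Ache, Bche, Chrm2, Chrna7, Ccr2, Il1b, Il6, Tnf, Col1a1 and Postn in every contrast. For injury under PBS, 1 of the 8 rises is not described and was left out of the search for libraries that stood apart. Other genes named in the text were chosen after their values were seen, as examples of a list or of a pattern.

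There were 41 gene lists with 719 genes, written from general knowledge, with 0 genes in more than 1 list. They covered sarcomere, cardiac ion handling, cardiac stress and fetal genes, fatty acid oxidation, the nuclear-encoded respiratory chain, mitochondrially encoded genes, the citric acid cycle, glycolysis, extracellular matrix, resting fibroblasts, macrophages, resident cardiac macrophages, recruited monocytes, neutrophils, T and NK cells, B cells, antigen presentation, mast cells, cytokines and chemokines, interferon-stimulated genes, complement, inflammasome and cell death, p53 targets, cell cycle, integrated and endoplasmic reticulum stress, diphthamide synthesis, heat shock, immediate early genes, the circadian clock, glucocorticoid-responsive genes, endothelium, smooth muscle and pericytes, cholinergic genes, adrenergic genes, Schwann cells and neurons, red cells and platelets, adipocytes, mesothelium, atrium, skeletal muscle, and male and female markers. Lists with at least 4 tested members were tested with limma camera on voom values, with a preset correlation between genes of 0.01, and adjusted over the lists of a contrast. Camera asks whether a list moved more than other genes. It was run again with the correlation estimated from the data. The fry test, which asks whether a list's genes move on balance one way, was run beside it and does not compare a list with other genes. Counts of called members are over all genes tested, and a second count is adjusted over the list alone.

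Library-level measures were total counts, the share of mitochondrially encoded reads, the share taken by the 10 most abundant genes, and the mean log2 CPM of cell type lists. They were compared by exact two-sided permutation tests of 6 against 6 libraries (924 arrangements), with 72 tests adjusted together. The injury share, in percent, projected a library's log2 CPM difference from the WT_PYR mean onto the DTR_PBS minus WT_PBS change. It was taken over genes called for injury under PBS. A library's own values were left out of the means it was set against. The genes themselves were called with all DTR_PBS libraries, which may raise the DTR_PBS shares. The covariance of the drug and injury effects was set beside 20 simulations without a drug effect, in which genes varied independently, and beside 10 splits of the DTR_PBS libraries into 3 and 3.

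Alternatives chosen before the data were examined were DESeq2 size factors, no filter on low counts, the authors' filtered genes, mitochondrially encoded genes left out, only the 12 libraries compared, the tag letter or tag series as a covariate, the DESeq2 Wald test, limma voom without and with sample quality weights, and leaving out each of the 24 libraries. Chosen after the data were seen were total-count scaling, 1 surrogate variable (svaseq) as a covariate, and leaving out DTR_PYR 4, 5 and 6 together. Within-group structure was examined by principal components with GC content and transcript length from the reference, with 500 genes at each end, and after thinning all libraries to 1877914 reads. The number of genes parting all DTR from all WT libraries was set beside the numbers from the 455 choices of 3 libraries among DTR_PYR 4, 5 and 6 and the 12 WT libraries, joined to the other 9 DTR libraries. The number of genes found was also set beside 40 splits of the libraries per contrast.

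The edgeR pipeline was tested on simulated data with 200 changed genes among 15456. For injury under PBS it called 5.97% of genes changed 1.5-fold, 56.7% of those changed 2-fold and 84.8% of those changed 4-fold, with 5 of 15256 unchanged genes called. For pyridostigmine in injured hearts the shares were 5.97%, 49.3% and 81.8%, with 3 of 15256. Simulated genes varied independently, so these shares need not hold where genes vary together. Among the real injured libraries, another split called as many as 4386 genes. Duplicate libraries were checked for and none was found (smallest chi-squared per degree of freedom between libraries of a group, 6.07).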

Results

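Polyadenylated RNA from the apex of the ventricles was sequenced in 24 male C57BL/6 mice aged 10 weeks, taken at day 5. There were 4 groups of 6 animals. WT_PBS and WT_PYR hearts had no diphtheria toxin, and DTR_PBS and DTR_PYR hearts had an injury made with that toxin. PBS is the vehicle and PYR is pyridostigmine, a drug that blocks the cholinesterases, the enzymes that break down acetylcholine. DTR is the usual short form of the diphtheria toxin receptor, which lets the toxin enter and kill mouse cells; which cells carried it is not given in the sources used here. The genotype in the titles and the toxin moved together, so no comparison parts them, and "injury" below covers both.

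Total counts in M reads were 33.2, 3.73, 11.3, 14.6, 5.50 and 34.9 in WT_PBS 1 to 6 and 14.4, 11.4, 8.46, 7.24, 7.41 and 15.3 in WT_PYR 1 to 6. They were 36.3, 12.4, 8.41, 1.88, 7.23 and 8.07 in DTR_PBS 1 to 6 and 5.97, 2.81, 2.39, 9.66, 37.8 and 6.49 in DTR_PYR 1 to 6. Mitochondrially encoded genes took 4.59% to 25.6% of a library's counts. Animal tags ended in U or V, whose meaning is not given in the sources used here: each uninjured group held 4 U and 2 V libraries and each injured group 2 U and 4 V. In each uninjured group 2 of the 4 U animals had tags from a number series that no injured animal had, so differences within U libraries do not compare like tags throughout. The first principal component of log2 CPM took 44.2% of the variance and the second 12.7%. On the first, the 12 WT libraries lay between −57.2 and −35.1 and 9 of the 12 DTR libraries between 30.3 and 114. DTR_PYR 4, 5 and 6 lay at −35.4, −25.6 and −20.9, in or next to the WT range.

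**Figure D1:**
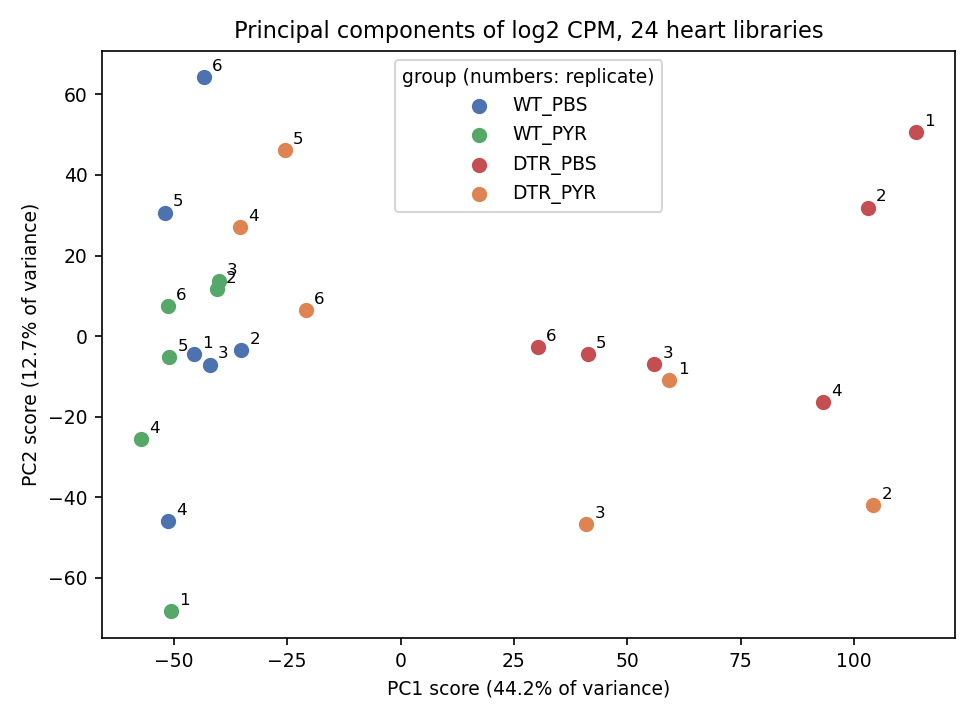
Scores of the 24 libraries on the first component (44.2% of variance) and the second (12.7%) of log2 CPM, coloured by group and numbered by replicate. DTR_PYR 4, 5 and 6 sit at −35.4 to −20.9 on the first component, and the other 9 DTR libraries at 30.3 or higher.

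The first comparison, DTR_PBS against WT_PBS, asked what the injury did without the drug. Most cardiac stress, matrix, cytokine and cell cycle genes rose and most genes of mitochondrial energy metabolism and cardiac ion handling fell, but with an estimated correlation none of the lists passed (smallest adjusted p 0.285). Fry, which does not compare a list with other genes, kept all 24 lists that camera called with the preset correlation. Nppb, the gene of B-type natriuretic peptide, a hormone released by stretched heart muscle (ENSMUSG00000029019, GRCm38 chromosome 4, 147985788 to 147987205), went from 206 ± 39.0 to 2641 ± 518 CPM (mean ± SD, n = 6 per group). Kcnip2, a subunit of the channel for the transient outward potassium current (ENSMUSG00000025221, chromosome 19, 45791839 to 45816061), went from 325 ± 48.4 to 26.8 ± 19.3 CPM. Hbegf, the mouse gene for heparin-binding EGF-like growth factor, whose human form is the toxin's receptor (ENSMUSG00000024486, chromosome 18, 36504929 to 36515805), went from 23.3 ± 3.21 to 133.9 ± 27.2 CPM. In edgeR 6634 of 15456 genes (42.9%) passed an adjusted p of 0.05, 3293 up and 3341 down, with 1951 up and 1386 down more than 2-fold. Among them, 3396 had no overlap between the libraries of the groups, 1711 up and 1685 down, where chance gives 0.216% of genes. For the injury effect under PBS, total-count scaling moved the median of all genes by 0.38 (log2) and gave 5705 genes up and 1756 down, so counts of falls are relative to TMM. No median of the 24 lists called by camera changed sign under that scaling or under DESeq2 size factors, here or for injury under pyridostigmine.

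The largest rises without overlap included secreted, matrix and stress genes. Chil3, a chitinase-like protein of activated macrophages, rose by 5.46 in log2 and Arg1, an arginase of the same cells, by 4.84. Spp1, the matrix cytokine osteopontin, rose by 4.93, from 20.2 ± 22.1 to 594 ± 550 CPM. Tnc, a matrix glycoprotein of healing tissue, rose by 4.90 and Timp1, an inhibitor of metalloproteinases, by 4.84. Sprr1a, a small proline-rich protein of stressed cells, rose by 5.16 and Ankrd2, a stretch-responsive muscle protein, by 4.85. The largest falls were Kcnv2, a modifier of potassium channels (−4.34), Snai3, a transcriptional repressor (−4.19), Kcnip2 (−3.61), Inmt, a methyltransferase of small amines (−3.22), Ces1d, a carboxylesterase (−3.08), Smco1, a membrane protein of muscle (−3.06), Cacna1s, a calcium channel subunit (−3.02), and Ky, a muscle peptidase (−2.96). Adjusted p lay at or below 0.00156 for these 15 genes, and all 6 libraries of DTR_PBS lay on one side of all 6 of WT_PBS.

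Of the 17 tested stress and fetal genes of the heart, 13 rose and 4 did not pass (13 up adjusted over the list alone). Camera adjusted p was 1.69e-07 with the preset correlation and 0.285 with an estimated correlation. Serpina3n, a protease inhibitor of the acute phase (ENSMUSG00000021091, chromosome 12, 104406729 to 104414329), rose from 12.2 ± 4.04 to 216 ± 39.7 CPM. Tnfrsf12a, the receptor of the cytokine TWEAK, rose by 3.41, Cilp, a matrix protein of loaded hearts, by 2.27, and Nppa, atrial natriuretic peptide, by 2.60. Myh7, the slow myosin of the fetal heart, did not pass (0.71, adjusted p = 0.207). In the extracellular matrix list 31 of 33 genes rose and 2 did not pass (31 up and 1 down adjusted over the list alone), with camera adjusted p 4.09e-14 and 0.285 with an estimated correlation. Ctgf, a growth factor of scarring, rose by 3.57, Tgfb2 by 3.19, Postn, periostin of activated fibroblasts, by 3.04 and Col1a1, the main scar collagen, by 2.74. Markers of resting fibroblasts split: 6 of 15 rose, 4 fell and 5 did not pass (7 up and 4 down adjusted over the list alone, camera 0.334, estimated correlation p 0.448). Mfap5, a microfibril protein, rose by 2.31 and Dpep1, a dipeptidase, fell by 0.83. The mean score of this list per library was 0.30 higher in DTR_PBS (exact permutation p = 0.00216, adjusted p = 0.0194, two-sided).

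Macrophage markers rose in 17 of 18 genes (18 adjusted over the list alone, camera 6.57e-09), with Itgam (3.64), an integrin of myeloid cells, and Ctss (3.36), a lysosomal protease. Genes of recruited monocytes rose in 14 of 16 and fell in 1 (camera 7.45e-06), led by Hmox1, which breaks down heme (3.80), Lgals3, a lectin of phagocytes (4.23), and Ccr2, the monocyte chemokine receptor (4.45). Markers of resident cardiac macrophages rose in 8 of 11 and fell in 1 (9 and 2 adjusted over the list alone, camera 0.00138); F13a1, a clotting factor subunit, rose by 1.80 and Igf1 by 1.61. Cytokines and chemokines rose in 24 of 29 and fell in 2 (26 and 2 adjusted over the list alone, camera 6.57e-09), among them Ccl2 (4.64), Il6 (5.65), Il1b (3.55) and Il33 (2.72), while Tnf rose by 1.69. Complement rose in 5 of 11 (camera 0.0129), with the receptors C5ar1 (3.03) and C3ar1 (3.07), and inflammasome and cell death genes rose in 15 of 20 and fell in 1 (17 and 1 adjusted over the list alone, camera 8.51e-06), with the sensor Nlrp3 (3.17) and the pore former Bax (1.48). With an estimated correlation the adjusted p of these 6 lists was 0.285. Neutrophil markers rose in 5 of 8 (camera 0.0064, estimated correlation p 0.295), with Lcn2, an iron-binding protein, at 3.83. Antigen presentation genes rose in 6 of 15 (7 adjusted over the list alone, camera 0.00598, estimated correlation p 0.364), with Itgax, an integrin of dendritic cells, at 2.85. T and NK cell (1 of 12 up; camera 0.459, estimated 0.785), B cell (3 of 10 up, 1 down; 0.278, estimated 0.511), mast cell (0 of 4; 0.533, estimated 0.685) and interferon-stimulated lists (2 of 23 up, 2 down; 0.523, estimated 0.868) did not pass.

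Mean marker scores per library moved with these genes. The macrophage score was 2.11 log2 units higher in DTR_PBS than WT_PBS and the recruited monocyte score 2.88 higher, and the endothelial score was 0.44 lower (exact permutation p = 0.00216 for each, the smallest the design allows, adjusted p = 0.0194, two-sided). The sarcomere score was 0.50 lower (adjusted p = 0.0486, exact test). Within U and V libraries the macrophage differences were 2.60 and 1.94 and the endothelial ones −0.53 and −0.35.

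Most genes of mitochondrial energy metabolism fell. Fatty acid oxidation genes fell in 24 of 25 (24 down and 1 up adjusted over the list alone, camera 6.67e-10), with Acadl, a long-chain dehydrogenase, going from 873 ± 97.0 to 312 ± 101 CPM. Nuclear-encoded respiratory chain genes fell in 41 of 44 (42 adjusted over the list alone, camera 2.91e-12), including Ndufs1 of complex I (−1.60) and Sdha of complex II (−1.49). Citric acid cycle genes fell in 16 of 18 (17 adjusted over the list alone, camera 2.54e-07), with Fh1, fumarase, at −1.16. With an estimated correlation the adjusted p of these 3 lists was 0.285. All 12 tested mitochondrially encoded genes fell (12 adjusted over the list alone), with mt-Nd1 at −1.47 and mt-Co3 at −2.14 (camera 0.00138, estimated correlation p 0.364). Their share of a library's counts, 7.13 ± 1.60% in DTR_PBS and 14.4 ± 6.87% in WT_PBS, did not pass (exact permutation test, adjusted p = 0.0985). Glycolysis genes went both ways, with 3 up, 10 down and 6 not passing (5 up and 11 down adjusted over the list alone, camera 0.115, estimated correlation p 0.511). The lactate exporter Slc16a3 rose by 2.79 and Pfkl, a phosphofructokinase, fell by 1.22. The median of the energy lists stayed negative under DESeq2 size factors and total-count scaling.

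Ion handling genes of the heart fell in 17 of 25 (17 adjusted over the list alone, camera 4.51e-06, estimated correlation p 0.291), with the pacemaker channel Hcn2 at −1.73 and the calcium channel Cacna1c at −1.38. Sarcomere genes fell in 10 of 24 and rose in 1 (12 and 2 adjusted over the list alone, camera 0.00659, estimated correlation p 0.511). Myl2, the ventricular regulatory light chain (ENSMUSG00000013936, chromosome 5, 122100951 to 122113472), fell from 7851 ± 901 to 2094 ± 794 CPM, Myh6, the fast adult myosin, fell by 1.33 and Myom2, an M-band protein, by 1.34. Endothelial markers fell in 11 of 18 and rose in 1 (camera 0.00138, estimated 0.285), with the receptors Tie1 (−1.10) and Kdr (−1.41) and the adhesion protein Cdh5 (−0.70). Under total-count scaling 4 endothelial genes were down and 8 sarcomere genes were down with 5 up. Smooth muscle and pericyte markers fell in 5 of 14 and rose in 2 (6 and 3 adjusted over the list alone, camera 0.0372, estimated 0.285), with the pericyte channel subunits Abcc9 (−1.90) and Kcnj8 (−1.09).

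Most cell cycle, p53, integrated stress and immediate early genes rose. Cell cycle genes rose in 29 of 30 (camera 3.04e-12), with Plk1, a mitotic kinase, at 3.72 and Cdk1 at 3.68. Targets of p53 rose in 8 of 12 and fell in 2 (camera 0.00138): Cdkn1a, which halts the cell cycle, went from 29.6 ± 8.88 to 536 ± 167 CPM and Eda2r, a death-domain receptor, rose by 3.28. Integrated stress genes rose in 15 of 24 and fell in 2 (15 and 3 adjusted over the list alone, camera 0.00129), with the transcription factors Atf4 (2.35) and Atf3 (3.93). Immediate early genes rose in 12 of 15 (12 up and 1 down adjusted over the list alone, camera 2.68e-05), with Egr2 at 4.15 and Junb at 2.25. With an estimated correlation the adjusted p of these 4 lists was 0.285. Glucocorticoid-responsive genes rose in 7 of 12 and fell in 2 (camera 0.0361, estimated 0.426), with Mt2, a metal-binding protein, at 3.52. Heat shock genes rose in 4 of 14 (camera 0.122, estimated 0.364), with the chaperones Hsp90aa1 (2.06) and Hspa1a (3.26). In the list for diphthamide, the residue the toxin modifies on elongation factor 2, Eef2k, the kinase of that factor, fell by 1.27 while Dph5 (1.23) and Dph2 (0.54) rose (camera 0.888, estimated 0.91). Circadian genes went both ways, 5 up and 5 down of 17 (camera 0.992, estimated 0.996); their median was −0.19, their mean 0.18, and camera and fry gave opposite signs.

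Nerve and transmitter genes were read because the drug acts on acetylcholine. Of 29 cholinergic genes 11 were tested and 4 fell (4 adjusted over the list alone, camera 0.162, estimated 0.448). Lynx1, which restrains nicotinic receptors, went from 414 ± 57.0 to 120 ± 45.9 CPM, and the receptor subunits Chrna10 (−1.77) and Chrna2 (−1.71) and the collagen tail Colq (−1.07) fell. Ache, acetylcholinesterase (−0.63, adjusted p = 0.109), Bche, butyrylcholinesterase (−1.07, 0.0714), and Chrm2, the muscarinic receptor of the heart (0.42, 0.182), did not pass. Chrna7, the nicotinic receptor of macrophages, was too low to test, with 9 reads in 24 libraries. Adrenergic genes fell in 7 of 14 and rose in 1 (camera 0.0211, estimated 0.285), with the receptors Adra2b (−2.51) and Adra1b (−1.77). In the Schwann cell and neuron list 4 of 11 rose and 2 fell (camera 0.556, estimated 0.594; median −0.03, mean 0.48), and Tubb3, a neuronal tubulin, rose by 3.38. Red cell and platelet markers split (2 up, 4 down of 8, 2 and 5 adjusted over the list alone, camera 0.758, estimated 0.91): the platelet gene Pf4 rose by 2.17 and the globin Hbb-bt fell by 1.93. Atrial markers fell in 2 of 6 (camera 0.134, estimated 0.285), among them Stard10, a lipid transfer protein (−1.78). The mesothelial list (0 of 8; camera 0.758, estimated 0.91; median −0.24, both tests up) and the male and female list (0 of 5; 0.632, estimated 0.868; median −0.11, both tests up) had none. Of 3 tested adipocyte genes Plin4, a lipid droplet protein, fell by 0.99, and of 3 skeletal muscle genes Myoz1 (4.46) and Tnnt3 (1.56) rose.

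The second comparison, DTR_PYR against WT_PYR, asked what the injury did in animals given pyridostigmine. Most cardiac stress, matrix, macrophage and cytokine genes rose here too, with a wide spread between libraries, and fewer metabolic genes passed. Nppb went from 247 ± 86.7 to 1745 ± 1417 CPM (n = 6 per group), Serpina3n from 11.2 ± 2.82 to 142 ± 109 and Hbegf from 22.7 ± 2.22 to 85.6 ± 71.0. Myl2 fell from 8038 ± 1047 to 2795 ± 559 CPM. In edgeR 1891 genes (12.2%) passed, 1246 up and 645 down, with 772 up and 118 down more than 2-fold, and 616 of them had no overlap between groups (274 up, 342 down; chance share 0.216%). For the injury effect under PYR, limma voom called 787 genes, and leaving out DTR_PYR 4, 5 and 6, a choice made after the data were seen, gave 5027. A larger injury response is built into that choice, since these 3 had the lowest injury shares in DTR_PYR. Leaving out DTR_PYR 1, 2 or 3 gave 744, 750 or 1110, WT_PYR 1, 4 or 6 gave 1244, 1091 or 1254, and the highest count, 2699, came without DTR_PYR 4.

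**Figure D2:**
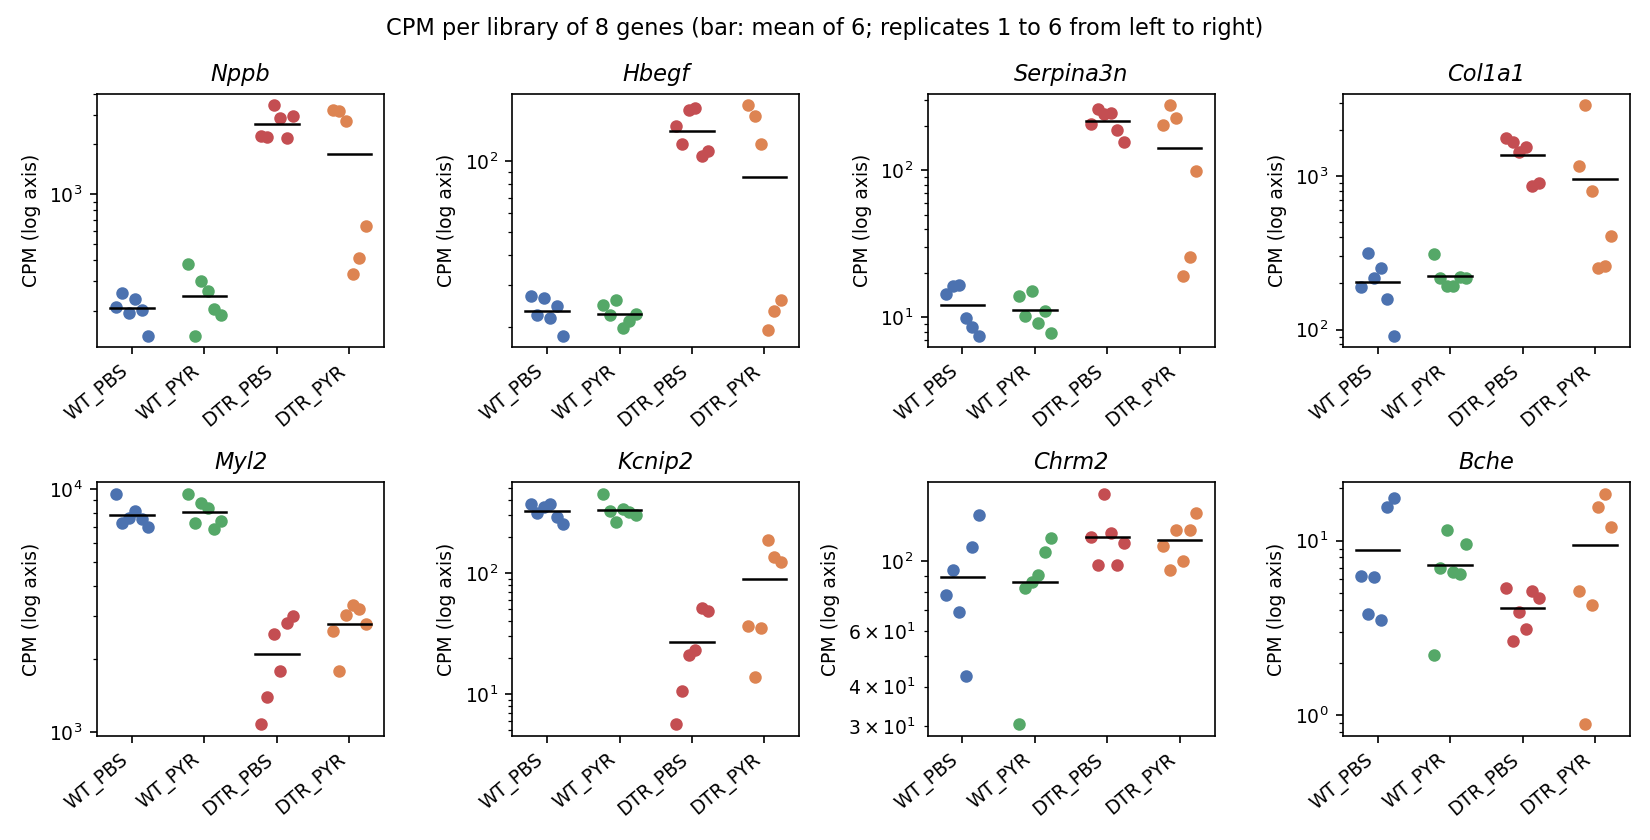
CPM of 8 genes in each of the 24 libraries by group on a log axis, with a bar at the mean of 6. In DTR_PYR the 6 libraries of Nppb and Hbegf spread widely (SD 1417 and 71.0 CPM), while Myl2 lies below every WT library in all 12 DTR libraries.

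The largest rises without overlap began with Ptx3, an acute-phase pentraxin (4.48), Serpina3n (3.65) and Otud1, a deubiquitinase (3.5). Egr2 (3.41) and Fos (2.98), immediate early transcription factors, Hspa1a, an inducible chaperone (3.05), Nmrk2, which makes NAD from nicotinamide riboside (2.85), and Eda2r (2.72) came next. Falls were smaller: Snai3 (−1.94), Kcnip2 (−1.90), Sbk2, a muscle kinase (−1.62), Lrrc4b, a synaptic adhesion protein (−1.61), Myl2 (−1.52), Hdac11, a deacetylase (−1.52), Ky (−1.49) and Cacna1s (−1.49). Adjusted p lay at or below 0.0479 for these 16 genes, and the 6 DTR_PYR libraries lay on one side of the 6 WT_PYR ones for each. Nppa (1.93), Col1a1 (2.1), Postn (1.89), Ccr2 (2.59), Il1b (2.84) and Il6 (3.73) also rose. Myh6 (−0.70, adjusted p = 0.16), Myh7 (1.21, 0.0733), Tnf (1.46, 0.102), Ache (−0.53, 0.253), Bche (0.46, 0.532) and Chrm2 (0.44, 0.234) did not pass.

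Matrix genes rose in 25 of 33 (29 up and 1 down adjusted over the list alone, camera 4.88e-14, estimated correlation p 0.25), led by Thbs1, a matrix thrombospondin (3.52), and Ctgf (2.59). Stress and fetal genes rose in 11 of 17 (14 adjusted over the list alone, 4.08e-09, estimated 0.199) and macrophage markers in 16 of 18 (17 adjusted over the list alone, 5.2e-07, estimated 0.449), with Cd68, a lysosomal protein of phagocytes, at 2.56. Cytokines rose in 20 of 29 (22 adjusted over the list alone, 0.000335, estimated 0.453), with the chemokines Ccl7 (3.47) and Cxcl10 (3.51). Recruited monocyte genes rose in 10 of 16 (11 adjusted over the list alone, 0.0147, estimated 0.488) and resident macrophage genes in 6 of 11 (6 up and 1 down adjusted over the list alone, 0.000483, estimated 0.177). Immediate early genes rose in 11 of 15 (13 adjusted over the list alone, 9.04e-10, estimated 0.177), p53 targets in 7 of 12 (8 up and 1 down adjusted over the list alone, 0.000216, estimated 0.136) and cell cycle genes in 12 of 30 (25 adjusted over the list alone, 7.8e-05, estimated 0.453), with Top2a at 2.38. Heat shock (5 of 14 up; 0.00283, estimated 0.198), complement (3 of 11 up, 4 adjusted over the list alone, 0.0417, estimated 0.452), inflammasome (3 of 20 up and 1 down, 6 and 1 adjusted over the list alone, 0.0166, estimated 0.453) and glucocorticoid lists (4 of 12 up, 7 adjusted over the list alone, 0.0408, estimated 0.453) also passed camera upward.

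Fatty acid oxidation genes fell in 2 of 25 (0 adjusted over the list alone, camera 6.01e-08, estimated 0.449), with Hadh at −0.86, respiratory chain genes in 3 of 44 (0 adjusted over the list alone, 1.33e-10, estimated 0.449), with Sdha at −0.68, and citric acid cycle genes in 3 of 18 (7 adjusted over the list alone, 7.9e-07, estimated 0.449), with Cs, citrate synthase, at −0.66. Ion handling fell in 4 of 25 (4 adjusted over the list alone, 1e-04, estimated 0.453), among them the pacemaker channel Hcn4 (−1.35). Sarcomere genes fell in 3 of 24 and rose in 1 (4 and 1 adjusted over the list alone, 0.0167, estimated 0.547). Endothelial markers fell in 5 of 18 (10 adjusted over the list alone, 2.9e-07, estimated 0.136), with Cdh5 at −0.61, and smooth muscle markers in 2 of 14 (5 adjusted over the list alone, 0.00763, estimated 0.25). Camera also put glycolysis (3 up, 1 down of 19, 3 and 4 adjusted over the list alone, 0.0166, estimated 0.453), mast cell (0 of 4; 0.0167, estimated 0.25) and mesothelial lists (0 of 8; 0.00278, estimated 0.453) lower and the male and female list higher (0 of 5; 0.047, estimated 0.453). The mitochondrially encoded list did not pass (0 of 12; camera 0.415, estimated 0.83; median −0.08, mean 0.12). Without DTR_PYR 4, 5 and 6, falls passed in 23 of 25 fatty acid oxidation genes, 29 of 44 respiratory chain genes and 16 of 18 citric acid cycle genes, and rises in 30 of 33 matrix and 27 of 30 cell cycle genes. That choice drops the lowest injury shares in DTR_PYR, so a larger injury response is built into it. Without these 3 libraries the median changed sign in 2 of the 24 lists called by camera, the mast cell and the male and female lists. With all libraries, fry kept 9 of the 24 lists.

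The remaining lists did not pass camera under pyridostigmine. These were resting fibroblast (4 up, 1 down of 15; camera 0.279), neutrophil (1 of 8 up; 0.251), T and NK cell (1 of 12 up; 0.919), B cell (2 of 10 up; 0.992) and antigen presentation genes (3 of 15 up; 0.127). So were the interferon (1 of 23 up; 0.357), integrated stress (7 of 24 up; 0.0863), diphthamide (1 up, 1 down of 8; 0.29), circadian (1 up, 1 down of 17; 0.992), cholinergic (1 of 11 down; 0.11), adrenergic (1 of 14 down; 0.182), Schwann cell (1 of 11 up; 0.457), red cell (1 of 8 up; 0.771) and atrial lists (1 of 6 down; 0.053). Estimated correlation p lay at or above 0.25 for these 14. Adjusted over the list alone the counts differed from these for resting fibroblast (5 up, 3 down), integrated stress (9 up, 1 down) and adrenergic genes (1 up, 2 down). Median and test had opposite signs in the B cell and red cell lists, and median and mean in the Schwann cell list. Called members included Atf4 (1.78), Lcn2 (3.05), Zbp1, a sensor of nucleic acids (2.49), Lynx1 (−1.10), Adra1b (−1.14), Tubb3 (2.46) and Myoz1 (2.88). The macrophage score was 1.29 higher and the endothelial score 0.41 lower in DTR_PYR than WT_PYR (adjusted p = 0.0416 and 0.0194, exact two-sided permutation tests); within U and V libraries the macrophage differences were 2.68 and 0.46. The recruited monocyte score did not pass (1.43 higher, adjusted p = 0.192, exact test) and was 3.43 higher within U and 0.05 lower within V libraries. The neutrophil score, 0.78 higher, did not pass either (adjusted p = 0.375, exact test).

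The 2 injury responses, which share no library, were then set side by side. Across 15456 genes, which are not independent replicates, their log2 fold changes had r = 0.811 (jackknife SE over libraries 0.123), and r = 0.845 with the tag letter as a covariate. Of the genes called under pyridostigmine, 93.8% were called under PBS. All 1773 called in both had the same sign, 1165 up against 265.5 if independent and 608 down against 139.4. The slope of the pyridostigmine response on the PBS response was 0.56 over genes called under PBS. Choosing genes by their PBS change lowers such a slope even where both responses are equal. DTR_PYR 4, 5 and 6, which lay in or next to the WT range on the first component, also enter it. Across all 24 libraries, 163 genes parted every DTR from every WT library, 55 higher and 108 lower. Without DTR_PYR 4, 5 and 6 the number was 2289. They included, chosen as examples after their values were seen, Fos, Serpina3n, Igf1 and Vcan, a matrix proteoglycan, on the higher side and Myl2, Kcnip2, Cs and Aqp1, a water channel, on the lower.

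The third comparison, DTR_PYR against DTR_PBS, is the question of the series title: what pyridostigmine did to injured hearts. No gene passed edgeR's threshold. Nppb averaged 1745 ± 1417 CPM with the drug and 2641 ± 518 without (log2 difference −0.60, SE 0.41, n = 6 per group, adjusted p = 0.417). Ccr2 averaged 12.9 ± 12.8 and 45.0 ± 42.7 CPM (−1.86, adjusted p = 0.148), Postn 63.3 ± 33.5 and 143 ± 67.9 (−1.20, 0.134) and Bche, one of the drug's targets (ENSMUSG00000027792, chromosome 3, 73635808 to 73708415), 9.41 ± 7.01 and 4.14 ± 1.10 (1.23, 0.178). Ache, the other (ENSMUSG00000023328, chromosome 5, 137287519 to 137294466), averaged 3.03 ± 1.13 and 2.55 ± 1.01 CPM (0.32, 0.593), and Chrm2, the receptor through which acetylcholine slows the heart (ENSMUSG00000045613, chromosome 6, 36388084 to 36528414), 117 ± 17.9 and 119 ± 24.6 (−0.03, 0.958). In edgeR 0 genes were called, with 2991 at an unadjusted p under 0.05 where 772.8 are expected by chance, and a smallest adjusted p of 0.1. For the pyridostigmine effect in injured hearts, DESeq2 called 242 genes (172 up, 70 down) and limma voom 1765 (625 up, 1140 down), or 2207 with quality weights. Leaving out DTR_PYR 2 gave 2404 in edgeR, leaving out DTR_PBS 6 gave 30, DTR_PYR 1 gave 15, and DTR_PBS 3 or WT_PYR 5 gave 1 each.

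Among genes of at least 5 CPM, the 8 smallest p values began with Acot1, an acyl-CoA thioesterase. It averaged 8.84 ± 7.01 CPM with the drug and 2.37 ± 1.13 without (1.92, adjusted p = 0.1). Enc1, an actin-binding protein, averaged 16.5 ± 3.82 and 28.0 ± 2.95 (−0.78, 0.1). Next were Eef2k (51.8 ± 10.1 and 32.0 ± 5.88; 0.71, 0.111), Foxo4, a transcription factor of stress and ageing (46.0 ± 13 and 26.3 ± 8.37; 0.82), and Scarf1, an endothelial scavenger receptor (24.2 ± 4.02 and 14.2 ± 3.77; 0.78). Olfml2a, a secreted olfactomedin protein (1.0), Dok4, a docking protein (0.94), and Polh, a repair polymerase (−0.83), had adjusted p 0.131, as had Foxo4 and Scarf1. Hbegf averaged 85.6 ± 71.0 against 134 ± 27.2 CPM (−0.66, adjusted p = 0.332), with DTR_PYR 4, 5 and 6 at 19.3, 23.3 and 25.8 CPM and DTR_PYR 1, 2 and 3 at 171.9, 155 and 118. Nppa (−0.26), Col1a1 (−0.50), Il1b (−1.27), Il6 (−1.45), Tnf (−0.28), Myh6 (0.67) and Myh7 (0.74) had adjusted p from 0.232 to 0.812. There were 58 genes without overlap between groups, 0.216% of genes being the chance share.

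Camera with the preset correlation put 23 lists past 0.05, and 0 passed with an estimated correlation (smallest adjusted p 0.319). Lists lying higher with the drug were fatty acid oxidation (median 0.68; 19 of 25 adjusted over the list alone, 1.71e-07), respiratory chain (0.44; 4.45e-08), citric acid cycle (0.48; 0.000102), mitochondrially encoded genes (1.01; 12 of 12 adjusted over the list alone, 0.00184), ion handling (0.57; 13 up and 1 down of 25 adjusted over the list alone, 3.58e-06), sarcomere (0.36; 0.000492) and adrenergic genes (0.35; 1 of 14 adjusted over the list alone, 0.013). The mitochondrial fatty acid importer Cpt1b stood at 0.94, Acadl at 0.67, mt-Nd1 at 0.96 and mt-Co3 at 1.43. Lists lying lower were cell cycle (median −0.99; 8 of 30 adjusted over the list alone, 1.25e-15), cytokines (−0.83; 1.95e-12), matrix (−0.69; 2.33e-09), recruited monocytes (−0.95; 3.97e-08), macrophages (−0.61; 4.9e-08), inflammasome (−0.53; 9.26e-07), integrated stress (−0.47; 1 of 24 adjusted over the list alone, 7.6e-05), antigen presentation (−0.39; 0.000263), neutrophils (−0.78; 0.000579) and p53 targets (−0.49; 0.00233). Cdk1 stood at −1.76 and the kinetochore motor Cenpe at −1.68. Immediate early (−0.47; 3 of 15 adjusted over the list alone, 0.00321), stress (−0.37; 1 of 17 adjusted over the list alone, 0.00327), complement (−0.57; 0.0135), mesothelial (−0.67; 0.0177), T and NK cell (−0.27; 0.0344) and glucocorticoid lists (−0.33; 0.0485) followed. Estimated correlation p of the 23 lists lay between 0.319 and 0.404.

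Fry gave an adjusted p under 0.05 for 13 of the 23 lists, among them cytokines (0.00436), p53 targets (0.00436), cell cycle (0.00858), matrix (0.0348) and ion handling (0.0499), but not fatty acid oxidation (0.0672). Without DTR_PYR 4, 5 and 6, left out after the data were seen, 0 genes passed, and the median changed sign in 10 of the 23 lists, including macrophages (0.11), stress genes (0.20), mitochondrially encoded genes (−0.22) and T and NK cells (0.62). It was 0.03 for fatty acid oxidation, 0.11 for ion handling, −0.01 for matrix, −0.05 for cytokines, −0.21 for recruited monocytes and −0.25 for cell cycle. The libraries left out had the lowest injury shares in DTR_PYR (10.3%, 16.9% and 23.5%, against 70.6% to 117% in DTR_PYR 1, 2 and 3). A shift towards DTR_PBS is built into leaving them out, so these medians do not test the drug effect. Total-count scaling moved the median of all genes by −0.15 and changed the sign in 0 of the 23 lists. Among lists camera did not call, the cholinergic one had a median of 0.32 (2 of 11 adjusted over the list alone, Lynx1 at 0.83 and Chrna2 at 1.65; camera 0.126, estimated 0.404), smooth muscle 0.38 (3 of 14 adjusted over the list alone, 0.0781), resident macrophages −0.34 (2 of 11 adjusted over the list alone, 0.0622), B cells −0.56 (0.0533), red cells −0.78 (0.0613) and endothelium 0.16 (0.0999). Glycolysis (1 of 19 adjusted over the list alone), atrial, interferon, Schwann cell, resting fibroblast, mast cell, male and female, diphthamide (1 of 8 adjusted over the list alone), heat shock and circadian lists had camera adjusted p from 0.178 to 0.939. Estimated correlation p of all these lists was 0.399 or higher. Fry called 2 of them, resident macrophages (0.0373) and B cells (0.0325). Median and mean differed in sign for interferon, heat shock and circadian genes, and median and test for mast cell genes. Adjusted over the list alone, 1 of 3 adipocyte genes was higher and 2 of 3 skeletal muscle genes were lower.

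**Figure D3:**
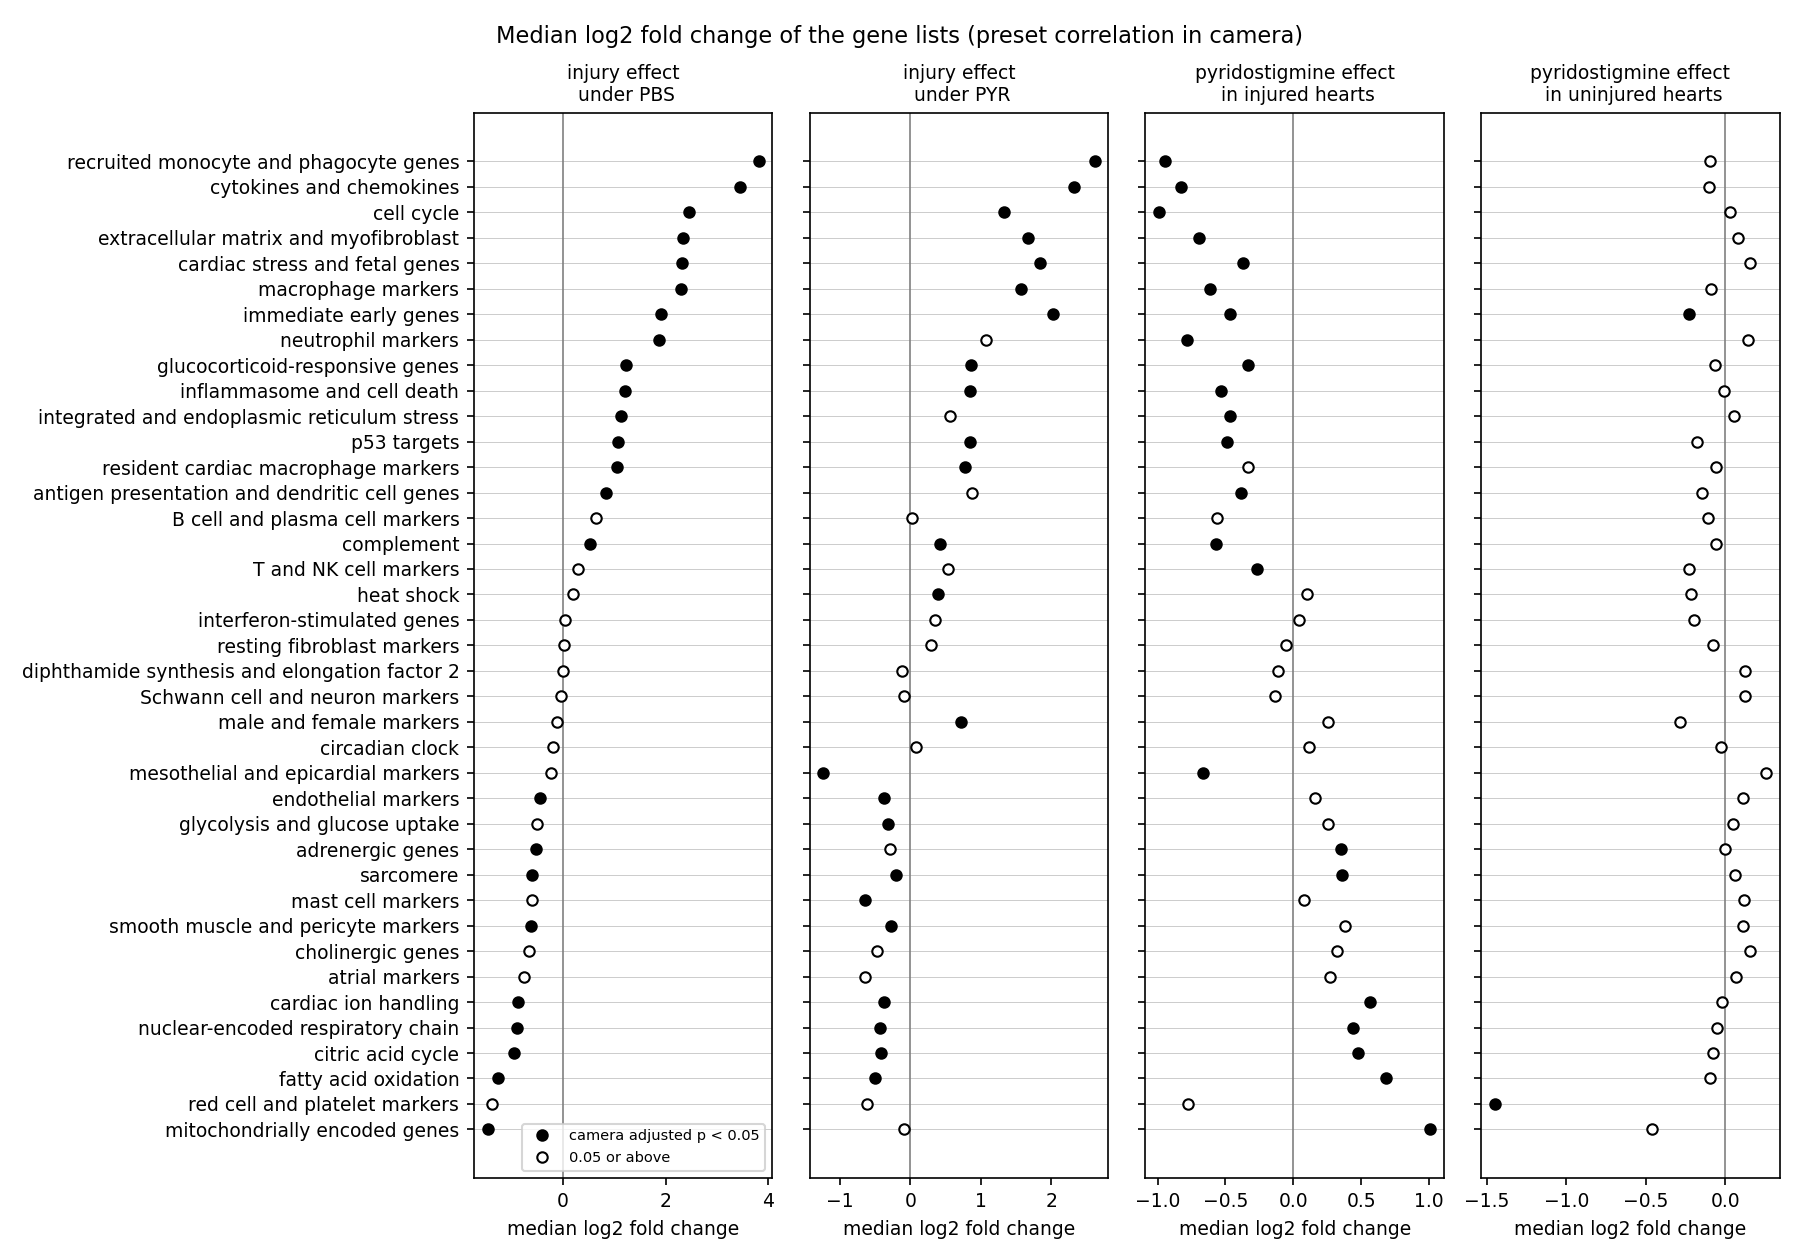
Median log2 fold change of the gene lists in 4 contrasts, filled where camera with the preset correlation gave an adjusted p under 0.05. With an estimated correlation the smallest adjusted p was 0.285, 0.136, 0.319 and 0.618 for the 2 injury and the 2 drug contrasts, and without DTR_PYR 4, 5 and 6 the median changed sign in 10 of 23 lists for the drug in injured hearts. Those libraries had the lowest injury shares in DTR_PYR, so a shift towards DTR_PBS is built into leaving them out.

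Among the library-level measures of this comparison 1 passed: the Schwann cell and neuron score was 0.38 lower with the drug (0.87 ± 0.24 against 1.25 ± 0.19, n = 6 per group, exact two-sided permutation p = 0.00433, adjusted p = 0.0312 over 72 tests). It was lower by 0.28 among U libraries and by 0.43 among V libraries. As means of log2 CPM these scores are low, and the groups held the shallowest libraries. Those were DTR_PBS 4, DTR_PYR 3 and DTR_PYR 2, with 1.88, 2.39 and 2.81 M reads. The score was not compared without DTR_PYR 4, 5 and 6. With injury the same score was 0.44 higher under PBS (adjusted p = 0.0389) and 0.12 lower under pyridostigmine (adjusted p = 0.536, exact tests). Its members Tubb3 (−0.93, adjusted p = 0.199) and Mbp, a myelin protein (−0.75, 0.209), did not pass singly, and camera did not call the list (0.325, estimated 0.399).

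How far each injured heart carried the PBS injury response was measured as its injury share, with the mean DTR_PBS change as the unit. The share was 133%, 127%, 84.4%, 113%, 71.8% and 61.4% in DTR_PBS 1 to 6 and 86.0%, 117%, 70.6%, 10.3%, 16.9% and 23.5% in DTR_PYR 1 to 6. WT_PYR libraries lay between −7.98% and 7.88%. The means were 54.1 ± 43.6% with the drug and 98.4 ± 30.0% without. The difference of −44.3 points did not pass (exact two-sided permutation p = 0.0801, n = 6 per group). The genes were chosen by their change in the DTR_PBS libraries, which may raise the DTR_PBS shares and widen this difference. Among V libraries the difference was −55.8 points (exact p = 0.0571, 4 against 4) and among U libraries −21.3 (exact p = 0.667, 2 against 2, where 0.05 cannot be reached). Across all 15456 tested genes, the drug effect in injured hearts ran against the injury effect with r = −0.83 and covariance −0.422 (jackknife SE of r 0.154). Both contrasts share the DTR_PBS libraries, and simulations without a drug effect gave r = −0.17 on average (−0.18 at the lowest), but those let genes vary independently. With DTR_PBS split into 3 and 3, so that no library was shared, r averaged −0.65 (−0.74 to −0.42 over 10 splits). Genes are not replicates, and the test over animals is the one on the share.

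**Figure D4:**
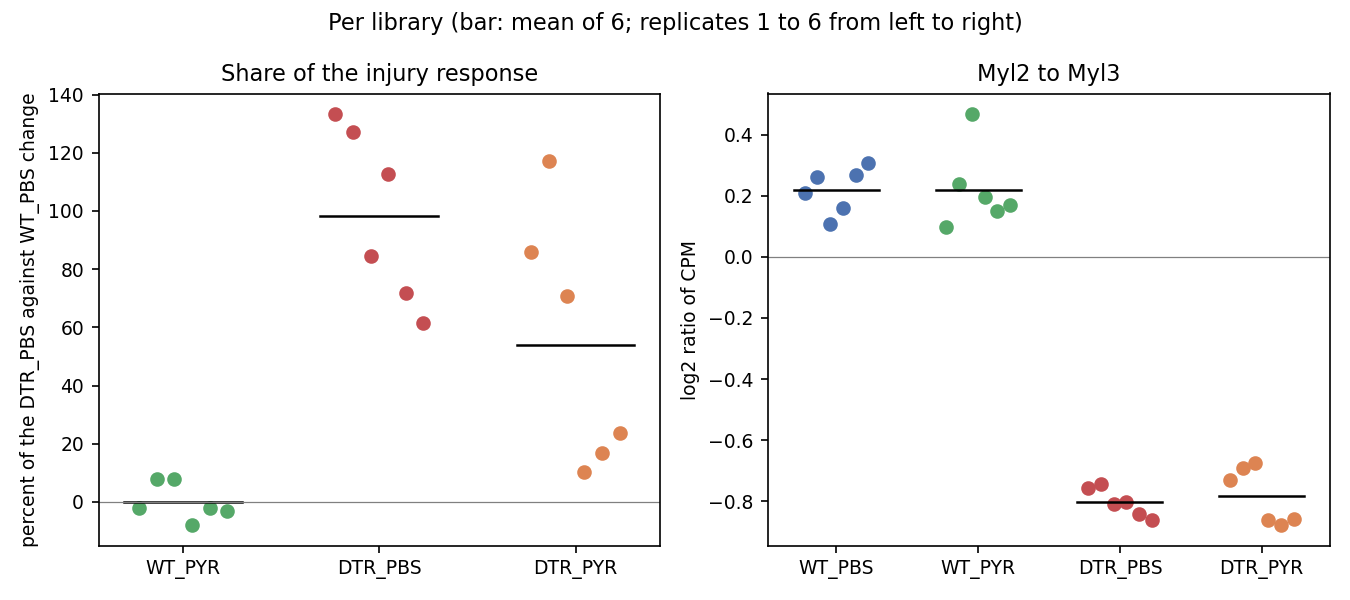
Injury share in percent and the log2 ratio of Myl2 to Myl3 for each library, by group. DTR_PYR 4, 5 and 6 have shares of 10.3% to 23.5% and DTR_PYR 1, 2 and 3 of 70.6% to 117%, while the ratio lies below every WT library in all 12 DTR libraries.

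The fourth comparison, WT_PYR against WT_PBS, asked what the drug did without injury. No gene passed. Ache averaged 4.52 ± 1.10 CPM with the drug and 3.87 ± 1.45 without (0.23), Bche 7.21 ± 3.17 and 8.82 ± 6.15 (−0.30) and Chrm2 85.8 ± 30.5 and 89.3 ± 33.9 (−0.06; n = 6 per group, adjusted p = 0.998 for the 3 genes). In edgeR 0 genes were called, with 481 at an unadjusted p under 0.05 against 772.8 expected; for the pyridostigmine effect in uninjured hearts DESeq2 called 1, voom 0 and voom with quality weights 9. The smallest adjusted p of any gene in edgeR was 0.891. Among genes of at least 5 CPM, the 8 with the smallest p values were all lower with the drug at adjusted p = 0.998. They were Nr4a1, an immediate early nuclear receptor (31.0 ± 12.5 against 73.8 ± 34.6 CPM; −1.27), Ube2w, a ubiquitin-conjugating enzyme (−1.02), Amd1, of polyamine synthesis (−0.93), Apold1, an endothelial early response gene (7.13 ± 1.10 against 13.5 ± 3.47; −0.91), Dnajb9, a chaperone of the endoplasmic reticulum (14.3 ± 1.71 against 24.5 ± 7.72; −0.79), Psmd14, of the proteasome (−0.60), Ppp3r1, of calcineurin (−0.58), and Tmem5, a glycosyltransferase (−0.50). There were 43 genes without overlap, the chance share being 0.216%.

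The other fixed genes lay close between these groups: Nppa (0.41), Nppb (0.26), Myh6 (0.04), Myh7 (0.24), Hbegf (−0.04), Il1b (−0.56), Il6 (0.48), Tnf (−0.05), Col1a1 (0.14), Postn (−0.04) and Ccr2 (−0.00). Camera called 2 lists, both lower with the drug. Red cell and platelet markers had a median of −1.45, with 5 of 8 lower when adjusted over the list alone (camera 4.8e-06, estimated correlation p 0.618): the globins Hbb-bt (9.16 ± 10.5 against 31.2 ± 26.9 CPM; −1.80), Hbb-bs (−1.54), Hba-a1 (−1.50) and Hba-a2 (−1.40) and the heme enzyme Alas2 (−1.56). Immediate early genes had a median of −0.23, with 1 of 15 lower when adjusted over the list alone (camera 0.0146, estimated 0.994). Fry called 0 of the 2 (0.753 and 0.97). The other lists tested had camera adjusted p of 0.135 or higher and estimated correlation p of 0.618 or higher. Their medians, means and tests differed in sign for ion handling, resident macrophages, recruited monocytes, neutrophils, B cells, inflammasome, integrated stress and circadian genes. Adjusted over the list alone, 1 gene was lower in each of the mitochondrially encoded, T and NK cell and integrated stress lists.

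The interaction asked whether the drug effect differed between injured and uninjured hearts. No gene passed in edgeR, with 1231 at an unadjusted p under 0.05 against 772.8 expected and a smallest adjusted p of 0.429. For the interaction of injury and pyridostigmine DESeq2 called 9 genes, voom 0 and voom with quality weights 3.8e+02 (rounded). Among genes of at least 5 CPM, the 8 with the smallest p values were all positive. They began with Kcnv2 (3.16, adjusted p = 0.429) and Acot1 (2.27, 0.429). At 0.464 were mt-Atp8, a subunit of ATP synthase (2.92), Atcay, a neuronal transport protein (2.21), and Gmnn, which limits DNA replication (1.55). Gfra1, a receptor for a nerve growth factor (1.16), Txndc16, a thioredoxin-like protein (1.14), and Sms, spermine synthase (0.77), were also at 0.464. Kcnv2 averaged 3.71 ± 3.37 CPM in DTR_PYR, 0.682 ± 0.445 in DTR_PBS, 9.38 ± 2.90 in WT_PYR and 12.5 ± 4.20 in WT_PBS. Bche (1.54, adjusted p = 0.599), Postn (−1.15, 0.607), Ccr2 (−1.86, 0.634), Il6 (−1.92, 0.74), Nppb (−0.86, 0.689), Nppa (−0.67, 0.739), Hbegf (−0.62, 0.741), Col1a1 (−0.64, 0.76), Il1b (−0.70, 0.847), Myh6 (0.63, 0.71), Myh7 (0.50, 0.834), Tnf (−0.23, 0.95), Ache (0.09, 0.964) and Chrm2 (0.03, 0.988) did not pass. The larger number of genes called for injury under PBS than under pyridostigmine was not matched by any single gene's interaction in edgeR.

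Camera with the preset correlation called 20 lists for the interaction and fry 0 of them, and estimated correlation p was 0.39 or higher. Mitochondrially encoded genes had a median of 1.42 (7 of 12 up adjusted over the list alone, camera 9.01e-05, estimated 0.39), fatty acid oxidation 0.78 (1 of 25 adjusted over the list alone, 1.68e-07, estimated 0.39), cell cycle −0.93 (7.02e-12, estimated 0.39) and matrix −0.65 (7.47e-11, estimated 0.39). Adrenergic genes had a median of 0.18 (2 of 14 adjusted over the list alone, 0.0116, estimated 0.39), which changed sign under total-count scaling, a setting that moved the median of all genes by −0.22. Without DTR_PYR 4, 5 and 6 the median changed sign in 6 of the 20 lists, but this drops the lowest injury shares in DTR_PYR and so does not test the interaction. Lists that camera did not call had adjusted p from 0.0546 (sarcomere) to 0.909 (circadian clock), and median and mean differed in sign for resting fibroblast, T and NK cell and circadian genes and median and test for interferon-stimulated genes.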

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

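The tests on a wrong label, on uneven toxin action and on Myl2 and the splits of the libraries were chosen after the results were seen; those on depth, GC content, transcript length and a smaller injury response were chosen before.

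Among 324 groups of 6 values, 17 held a library whose gap to the nearest other took an unusually large part of the group's range (Dixon's ratio). For independent, normally distributed values chance flags about 1 in 20 groups, and 17 is near that. Many of these groups are CPM of genes that vary together, so the number does not show that the libraries are alike. The ratio also cannot flag libraries that stand apart together, such as DTR_PYR 4, 5 and 6. Total counts stood apart in DTR_PBS 1 (36.318 M reads) and DTR_PYR 5 (37.842 M). DTR_PYR 2 held 4 of the 17, all high: Sprr1a 216, Spp1 646, Arg1 114.8 and Col1a1 2902 CPM. In DTR_PYR 6 the resting fibroblast score was 5.2618 (mean log2 CPM), Myh7 was 3614 CPM and Acot1 22.42. In DTR_PYR 3 Il6 was 5.458 and Apold1 26.9 CPM, and in WT_PYR 1 Col1a1 was 312.4 and Foxo4 58.02 CPM. The others were the red cell and platelet score of WT_PYR 3 (3.9775), Il6 in WT_PBS 3 (0.1932 CPM), Egr2 in DTR_PBS 4 (33.69) and Hspa1a in DTR_PBS 2 (45.68).

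For 20 gene lists camera with the preset correlation found that the drug effect differed between injured and uninjured hearts; fry found 0 of the 20 and estimated correlation p was 0.39 or higher. Median interactions (log2) were 0.5349 for ion handling, 0.7825 for fatty acid oxidation, 0.5249 for the respiratory chain, 1.415 for mitochondrially encoded genes, 0.5666 for the citric acid cycle and 0.178 for adrenergic genes. They were −0.5024 for stress and fetal genes, −0.6518 for matrix, −0.5824 for macrophages, −0.4018 for resident macrophages, −0.9342 for recruited monocytes, −0.8847 for neutrophils, −0.01223 for antigen presentation, −0.7034 for cytokines, −0.4197 for complement, −0.3578 for inflammasome, −0.2985 for p53 targets, −0.9287 for cell cycle, −0.4418 for integrated stress and −0.9157 for mesothelium. Without DTR_PYR 4, 5 and 6, the libraries with the lowest injury shares in DTR_PYR, the median changed sign in 6 of the 20. For the interaction of injury and pyridostigmine, 3 of 40 splits gave as many genes at an unadjusted p under 0.05, so chance cannot be excluded (real 1231, highest other 2590).

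DTR_PYR 4, 5 and 6 lay near the uninjured hearts on the first component (−35.4, −25.6 and −20.9) and had Hbegf at 19.3, 23.3 and 25.8 CPM, within the WT range of 18.3 to 26.8. All 3 had tags ending in V, as had DTR_PYR 3 with an injury share of 70.6%, while DTR_PYR 1 and 2 had U. Among DTR_PBS libraries the mean share was 123% with U and 86.2% with V. Leaving out the 3 therefore also changes the mix of tags, and the tag was not tested as a cause. A wrong label on all 3, as uninjured WT hearts, is argued against by 163 genes that parted all 12 DTR from all 12 WT libraries: when any 3 of these 3 and the 12 WT libraries joined the other 9 DTR libraries, 3 of 455 choices, the real one included, gave as many (mean of the others 8.44). The highest, 261, and the other one each held 2 of the 3 and a WT library, so part of the 163 may follow the spread among uninjured hearts. This count therefore cannot exclude a wrong label on 1 of the 3. The log2 ratio of Myl2 to Myl3, taken up after the data were seen, was −0.861, −0.878 and −0.859 in DTR_PYR 4, 5 and 6. It was 0.10 to 0.47 in WT libraries, which argues against a WT heart for each of the 3. A DTR heart without toxin is not excluded. Sequencing depth is argued against by all 3 libraries staying below the other 9 DTR libraries after thinning to 1877914 reads. A smaller injury response under pyridostigmine may account for the 3 libraries, but the lower injury share with the drug did not pass (exact permutation p = 0.0801, two-sided). Uneven toxin action unrelated to the drug also stays open: 3 of 6 DTR_PYR and 0 of 6 DTR_PBS libraries had Hbegf in the WT range (Fisher's exact p = 0.182, two-sided). The 2 cannot be told apart, because no measure of toxin delivery or cell loss apart from the RNA is given in the sources used here.

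Genes varied together within the uninjured groups along a component with 34.4% of that variance, and along it Chrm2 ran from 30.3 to 140 CPM and Ddx3y, a Y-linked helicase, from 4.5 to 65.3. GC content goes with it: the loadings of 15399 genes had rho = −0.689 with transcript GC, with medians of 40.1% and 55.1% in the 500 genes at either end, which may point to library preparation or RNA quality. Transcript length had rho = 0.242, which decides nothing, and depth is argued against, since the component kept a correlation of 0.998 with itself after thinning and had r = −0.00247 with depth (permutation p = 0.994, two-sided). The drug effect in uninjured hearts had rho = 0.454 with GC across genes, the largest of the 5 contrasts in size, so small differences there may follow this structure. For injury under PYR rho was −0.296, for injury under PBS −0.128, for the drug in injured hearts 0.157 and for the interaction −0.0969. How far the structure bears on genes called in those contrasts was not tested. No biological explanation was tested.

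Myl2 fell further than the rest of the sarcomere: −1.91 under PBS and −1.52 under pyridostigmine, against medians of −0.56 and −0.20 for the other 23 genes and lowest other values of −1.34 (Myom2) and −0.75 (Mybpc3). The excess of Myl2 over the median under pyridostigmine, −1.326, argues only against a loss of cardiomyocytes that lowers all these genes alike. The other 23 did not fall alike, and Myl2 was taken up after its values were seen, so the excess alone cannot decide on cell loss. The log2 ratio of Myl2 to Myl3, the essential light chain, lay at −0.68 to −0.88 in the DTR libraries, DTR_PYR 4, 5 and 6 included, and at 0.10 to 0.47 in the WT libraries, so that 12 of 12 DTR libraries were below every WT library. A difference carried by the DTR line, and not by the injury, is a candidate explanation. The ratio did not fall further with a larger injury share. It was −0.861, −0.878 and −0.859 in DTR_PYR 4, 5 and 6, with shares of 10.3% to 23.5%. In DTR_PBS 1 and DTR_PYR 2, with shares of 133% and 117%, it was −0.756 and −0.691. These values argue against a toxin effect on the ratio that grows with the injury share. A toxin effect of another kind cannot be told apart from the line, because there was no DTR heart without toxin.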

How the results depend on the processing

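Total-count scaling, 1 surrogate variable as a covariate and leaving out DTR_PYR 4, 5 and 6 together were chosen after the data were seen. Leaving out these 3, which had the lowest injury shares in DTR_PYR, selects on the outcome, so the changes it brings are partly built in. The injury effect under PBS stayed within 1.5 times of 6634 genes under the alternatives run, and between 5699 and 6928 when each of the 24 libraries was left out. For the injury effect under PYR (1891 genes) the count was 1232 without a filter on low counts, 1220 with only the 12 libraries compared, 787 with limma voom, 846 with voom and quality weights, 2920 with the tag letter and 2883 with 1 surrogate variable as covariate, and 5027 without DTR_PYR 4, 5 and 6. Leaving out single libraries gave 744 (without DTR_PYR 1) to 2699 (without DTR_PYR 4); beyond 1.5 times lay also DTR_PYR 2 (750) and 3 (1110) and WT_PYR 1 (1244), 4 (1091) and 6 (1254). For the pyridostigmine effect in injured hearts (0 in edgeR, 2991 at an unadjusted p under 0.05) the DESeq2 Wald test gave 242, voom 1765, voom with quality weights 2207 and 1 surrogate variable 196. Leaving out single libraries gave 0 to 2404, with 2404 without DTR_PYR 2, 30 without DTR_PBS 6, 15 without DTR_PYR 1 and 1 each without DTR_PBS 3 or WT_PYR 5; without DTR_PYR 4, 5 and 6 it was 0, with 885 at an unadjusted p under 0.05. For the pyridostigmine effect in uninjured hearts (0 in edgeR, 481 unadjusted) DESeq2 gave 1, voom 0 and voom with quality weights 9. For the interaction of injury and pyridostigmine (0, 1231 unadjusted) DESeq2 gave 9, voom 0 and voom with quality weights 3.8e+02 (rounded). Both stayed at 0 in edgeR whichever library was left out. The cause was not tested, except that a fit of 12 libraries has fewer samples and a fit without a filter tests more genes. Of the 132 genes named for injury under PBS, 2 no longer passed under each of voom with quality weights, no filter and total-count scaling, and under the other alternatives all tested did. Of 101 named under PYR, 40 no longer passed with voom, 41 with quality weights, 17 with only 12 libraries, 15 without a filter, 4 with the tag series, 2 with total-count scaling and 1 each with the tag letter, without mitochondrially encoded genes and without DTR_PYR 4, 5 and 6; no named gene changed sign. Of the lists camera called (24, 24, 23, 2 and 20 for the 5 contrasts), none passed with an estimated correlation and fry kept 24, 9, 13, 0 and 0; DESeq2 size factors ended no call, and the tag letter ended 2, 4, 3, 0 and 0. The smallest library, DTR_PBS 4, had 1.88 M reads, and what depth alone limits was not tested.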

Other observations

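The tests on splits of the libraries were chosen after the results were seen.

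The genes that parted all 12 DTR from all 12 WT libraries were found after the data were seen and hold for DTR_PYR 4, 5 and 6 too. Higher in every DTR library were Fos (28.0 to 122 CPM against 3.03 to 18.6 in WT), Serpina3n (19.2 to 277 against 7.48 to 16.6), Vcan (14.3 to 127 against 4.28 to 10.3), Igf1 (11.5 to 34.7 against 3.78 to 10.1), Tnfrsf12a (62.1 to 530 against 23.0 to 58.0) and Fstl1, a secreted factor of fibroblasts and epicardium (99.7 to 531 against 55.7 to 92.9). The nucleolar helicase Ddx21 (55.08 to 176.5 against 27.6 to 55) and Ftsj3, of ribosome assembly (35.1 to 83.5 against 19.8 to 32.5), were also higher. Lower in every DTR library were Cs (498 to 1332 against 1476 to 2077 CPM), Atp5b, the catalytic subunit of ATP synthase (1657 to 4696 against 5108 to 7264), Fhl2, a muscle LIM protein (225 to 1182 against 1205 to 1819), Aqp1 (151 to 403 against 414 to 675) and Kcnip2 (5.6 to 189 against 254 to 454). Their number was 163.

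Mitochondrially encoded genes took 7.13 ± 1.60% of counts in DTR_PBS and 14.4 ± 6.87% in WT_PBS, a difference of −7.22 points (n = 6 per group, exact two-sided permutation p = 0.0238, adjusted p = 0.0985), which did not pass.

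Other splits of the libraries gave the following. For injury under PBS, 1 of 40 splits, the real one, gave as many genes (real 6634, highest other 1427). That is the smallest share 40 splits can give, and the splits do not test the uneven tag letters. For injury under PYR it was also 1 of 40 (real 1891, highest other 1029). For pyridostigmine in injured hearts 6 of 40 splits gave as many genes at an unadjusted p under 0.05 (real 2991, highest other 5999), so chance cannot be excluded, and 5 of the other splits called genes at an adjusted p under 0.05 (4386, 1803, 879, 27 and 1), which points to a structure among the 12 injured libraries. For pyridostigmine in uninjured hearts 14 of 40 did (real 481, highest other 2467).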
